A study of Homo sapiens with 6 samples.

How the data were processed

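RNA from KYSE510 cells carrying a control shRNA (3 libraries) or a LOXL2 shRNA (3 libraries) was measured, with groups and replicate numbers read from the labels. Each file held 1 library. The expected count of each gene was deposited as an RSEM column, per the file headers, and was not scaled for depth. FPKM (fragments scaled for gene length and depth) was deposited beside it, also per the file headers, with genes listed from an FPKM of 0.01 upward. The submitters' processing notes name HISAT, Bowtie2 and RSEM without versions, and the build GRCh37. All listed transcripts carried RefSeq coding (NM) identifiers, a few of them under symbols of long intergenic noncoding RNA (LINC, 16 tested genes, 6 higher and 3 lower). The list of mitochondrially encoded genes had 0 genes to test. Reads shared between near-identical genes are divided by RSEM, so values of keratin, HLA, AKR1C, histone and CBS-like genes are uncertain.

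From these files 17453 genes were listed in any library, and 17416 were matched to a symbol by gene identifier through a RefSeq table of assembly GRCh38.p14. The 37 without a match held 0.069% to 0.118% of the expected counts of a library and were left out of named results. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 14314 and removed 3139. Library sizes were scaled by TMM (factors 0.94, 0.893 and 0.948 in the controls and 1.054, 1.094 and 1.089 in the LOXL2 shRNA libraries), and LOXL2 shRNA was compared with control shRNA by edgeR's robust quasi-likelihood test, two-sided, with a threshold of 0.05 on Benjamini-Hochberg adjusted p. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. The biological coefficient of variation was 13.3%. Log2 CPM for principal components and correlations used a prior count of 2.

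Gene lists were written before the data were examined: 35, of which 34 had at least 3 tested genes. They cover the lysyl oxidase family; matrix; matrix proteases; EMT; epithelial adhesion; basal squamous and squamous differentiation genes; actin; integrins; glycolysis, hypoxia, oxidative phosphorylation, cholesterol and fatty acid genes; interferon, antigen presentation and NF-kB genes. They also cover TGF-beta, YAP, EGFR, p53, unfolded protein, ATF4, NRF2 and heat shock genes, S phase, mitosis, histone, ribosomal and apoptosis genes, and markers of fibroblasts, leukocytes, endothelium and glandular epithelium. Each was tested with camera at a preset correlation of 0.01. HEK293 markers and neuronal and embryonic kidney genes were added after the data were seen. Named genes were, by a rule set before the data were examined, LOXL2 and its family, the 8 changed genes with the largest change in each direction, and at most 4 changed genes of smallest p per list. The 8 needed a mean of at least 5 CPM in the higher group and no overlap between the groups. Members said not to have passed are named beside a list. Folds against a group at 0 use a floor of 3 counts per library, and folds against 1 to 3 counts carry a 95% exact interval.

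The procedure was tested on simulated counts for LOXL2 shRNA against control shRNA (14167 genes). It recovered 24% of 50 genes changed 1.5-fold, 85.7% of 49 changed 2-fold, 97.9% of 48 changed 4-fold and 100% of 50 changed 8-fold. In all, 6 unchanged genes were called, and 0 genes when no change was simulated. The simulation gave every gene the same biological coefficient of variation and changed 200 genes, with directions drawn at random. The scaling and the error rate were therefore not tested where most genes change, as 62.1% did in the data. Alternatives were DESeq2; RLE, upper-quartile and total-count scaling; no filter; at least 1 CPM in 3 libraries; the replicate number as a block; length offsets with and without that block; limma on log2(FPKM + 1), with and without a filter at FPKM 1, and on log2(FPKM + 0.1); a test against a 1.5-fold change; and leaving out each of the 6 libraries. Lists were also tested with an estimated correlation, with fry and on ranks. Scaling to 42 epithelial genes with at least 20 CPM in the controls was added after the data were seen.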

Results

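RNA was sequenced from KYSE510, an established line of human esophageal squamous cell carcinoma, after stable lentiviral delivery of a short hairpin RNA (shRNA) against LOXL2 or of a scrambled control shRNA. The 6 libraries fell into 2 groups of 3 and were read on a BGISEQ-500. Expected counts per gene summed to 9841066, 9805836 and 9716812 in control replicates 1, 2 and 3. In LOXL2 shRNA replicates 1, 2 and 3 they summed to 9615230, 9830613 and 9633035. The control files listed 15497, 15569 and 15475 genes, and the LOXL2 shRNA files listed 16406, 16389 and 16374. The labels call the libraries of a group replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM (counts brought to a common library size, scaled by the trimmed mean of M-values, TMM), as mean ± SD over 3 libraries per group. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera.

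LOXL2 encodes a secreted copper-dependent amine oxidase that acts on lysines of collagen and elastin, and the comparison asks which transcripts differ when it is silenced. The targeted transcript (gene identifier 4017) stood at 647, 830 and 648 CPM in control replicates 1, 2 and 3 and at 76.8, 52.9 and 63.7 CPM in LOXL2 shRNA replicates 1, 2 and 3. Its mean fell from 708 ± 106 to 64.5 ± 12 CPM (SD, n = 3 per group), an 11-fold drop (log2 fold change −3.46, SE 0.18, edgeR adjusted p = 4.29e-07) resting on 19215 and 2014 counts. The 4 other measured members of the lysyl oxidase family moved in both directions. LOXL4 (84171) fell from 94.9 ± 39.5 to 17.6 ± 4.97 CPM (log2 fold change −2.43, SE 0.32, edgeR adjusted p = 0.000296) and LOX (4015), the founding member, from 75.2 ± 14.7 to 31.4 ± 5.75 CPM (−1.26, SE 0.17, edgeR adjusted p = 0.000166). LOXL1 (4016), which acts on elastin, rose from 4.73 ± 1.54 to 12.5 ± 0.637 CPM (log2 fold change 1.40, SE 0.22, edgeR adjusted p = 0.000389), and LOXL3 (84695) from 12.4 ± 1.40 to 27.9 ± 1.36 CPM (1.16, SE 0.13, edgeR adjusted p = 3.94e-05). With 2 members higher and 3 lower, also when adjusted over the list alone, the family as a list did not pass (camera adjusted p = 0.178). It passed on the DESeq2 fit (camera adjusted p = 0.0296, range 0.0296 to 0.637 over 20 camera alternatives) and in fry, which tests against no change (adjusted p = 0.023). In the same libraries 42 epithelial genes, described further on, stood at a median of 31.0% of their control level. On a scale that held those genes level, chosen after seeing the data, LOX turned direction (log2 fold change 0.41, edgeR adjusted p = 0.0234), while LOXL2 (−1.80) and LOXL4 (−0.78) stayed lower.

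**Figure D1:**
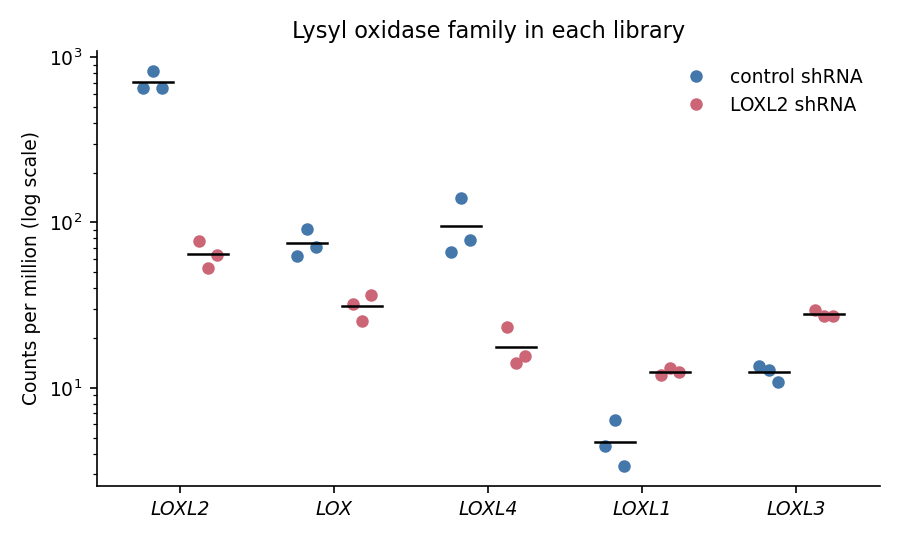
CPM (log axis) of the 5 lysyl oxidase family genes in each library, with blue points for control shRNA, red points for LOXL2 shRNA and a bar at each group mean. LOXL2 lay between 52.9 and 76.8 CPM in the LOXL2 shRNA libraries and between 647 and 830 in the controls; LOX, lower in the plot, was higher (log2 fold change 0.41) when libraries were scaled to the epithelial genes.

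The difference between the groups reached most of the expressed genes. Of 14314 genes tested, 8894 (62.1%) changed, 4783 upward and 4111 downward, and 2478 rose and 1683 fell by a log2 fold change of at least 1 in size. In 9773 genes (68.3%) the 3 libraries of 1 group all lay above the 3 of the other, where chance gives 10%. The changes ran strongly toward genes that the control cells did not express: 322 genes had a mean under 0.2 CPM in the controls and over 5 CPM in the LOXL2 shRNA libraries, and 1 gene, KLK11, had the reverse. Likewise 523 genes were listed in all LOXL2 shRNA files and no control file, against 43 the other way. The first principal component held 92.3% of the variance and separated the groups. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.983 to 0.993 within groups and 0.7862 to 0.8255 between them. Control replicate 2 stood apart on the second component, which held 3.9%, at −34.9 against 17.5 and 18.7 for the other controls. Tested against a 1.5-fold change instead of no change, 4761 genes passed, 2794 higher and 1967 lower. On the scale set by the 42 epithelial genes, 12965 genes were higher and 279 lower, and 2844 of the 8894 calls took the opposite sign.

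**Figure D2:**
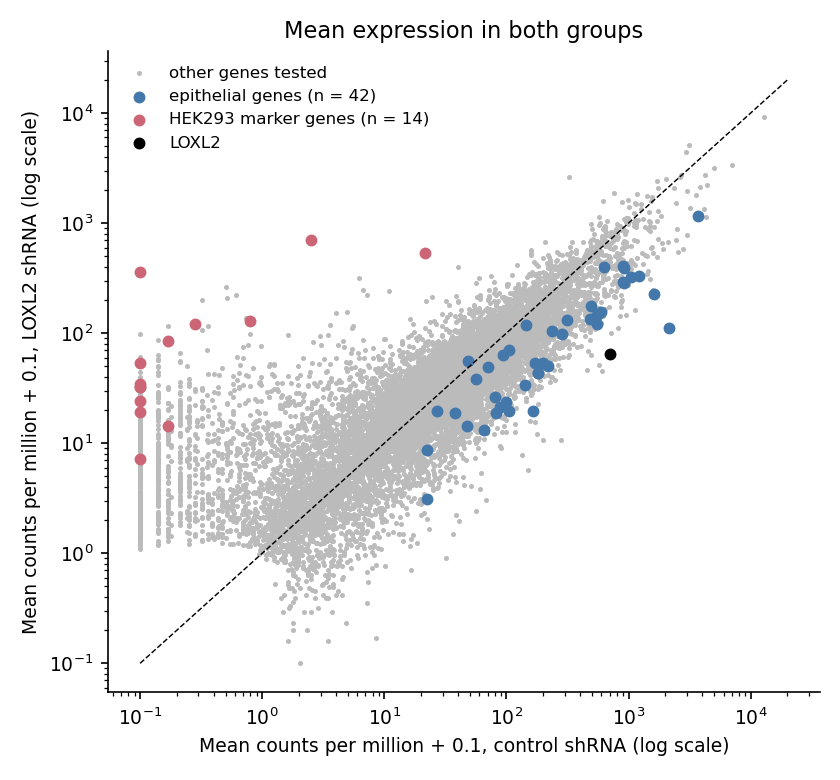
Mean CPM plus 0.1 of each tested gene in the control libraries (x, log axis) and the LOXL2 shRNA libraries (y, log axis), with the dashed line at equal levels. The 42 epithelial genes (blue) lie mostly below the line, at a median of 31.0% of the control level. LOXL2 (black) lies lower than all but 1 of them relative to the line. The 14 HEK293 marker genes (red), chosen after the largest rises had been seen, lie above the line. Scaled to the epithelial genes, the blue points centre on the line by construction.

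The 8 largest rises were all in genes with 0 counts in every control library, so their folds are lower bounds set against a floor of 3 counts per library, which covers counting error only. IRS4 (8471), an insulin receptor substrate, reached 358 ± 64.8 CPM (11187 counts, at least 1080-fold higher, edgeR adjusted p = 1.82e-07). VCAN (1462), the matrix proteoglycan versican, reached 97.3 ± 13.7 CPM and was at least 294-fold higher. EPB41L3 (23136), a membrane skeleton protein, stood at 60.8 ± 3.70 CPM (at least 184-fold), and NRN1 (51299), the neurite-promoting neuritin, at 58.3 ± 13.8 CPM (at least 176-fold). LIN28B (389421), an oncofetal RNA-binding protein that blocks let-7 maturation, stood at 53 ± 4.37 CPM (at least 160-fold). ATP8A1 (10396), a phospholipid flippase, and SLC7A3 (84889), a cationic amino acid transporter, were at least 120-fold and 112-fold higher. LOC102724560, at least 134-fold higher, is a near-identical copy of CBS with which it shares reads, so its value is uncertain. IRS4 and LIN28B are also among the 14 HEK293 marker genes, all higher in these libraries. Those markers were chosen after these rises had been seen, so the overlap is not independent evidence.

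The 8 largest falls, ranked by fitted change, had counts in every control library. KLK11 (11012), a secreted kallikrein protease, fell from 8.44 ± 2.69 CPM to 0.0658 ± 0.114 (edgeR adjusted p = 8.65e-06). With 228 control counts and 2 LOXL2 shRNA counts, both in replicate 1, it was lower by a ratio of 131 (95% exact interval 36 to 1090, counting error only). Without that replicate it was at least 29.8-fold lower. EDN2 (1907), the vasoconstrictor endothelin 2, fell by 5.28 on the log2 scale (SE 1.03, edgeR adjusted p = 0.00427), but control replicate 2 held 68.0 CPM against 15.1 and 11.6, and without it the change was −4.04. CLCA2 (9635), a chloride channel regulator of stratified epithelium, fell from 151 ± 11.2 to 5.66 ± 2.55 CPM (−4.74, SE 0.24, edgeR adjusted p = 4.26e-07). GJB6 (10804), the gap junction protein connexin 30, fell from 56.1 ± 0.971 to 2.30 ± 0.424 CPM (−4.60, SE 0.15, edgeR adjusted p = 4.23e-08). FABP4 (2167), a fatty acid carrier, fell from 7.13 ± 2.15 to 0.253 ± 0.143 CPM. CYP2B6 (1555), a drug-metabolising cytochrome, was at 281 ± 34.8 and 10.5 ± 8.88 CPM (log2 fold change −4.75, and −5.70 without LOXL2 shRNA replicate 1). SERPINA1 (5265), which encodes alpha-1-antitrypsin, and ATOH8 (84913), a bHLH transcription factor, changed by −4.74 and −4.67 on the log2 scale, and by −4.03 and −3.92 without control replicate 2. Beside these falls, 40 of the 42 epithelial genes were lower.

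For the 34 gene lists tested, all fixed before the data were examined, 3 lists were higher and 18 lower by camera with its preset correlation, and 0 passed with a correlation estimated per list (5 at an unadjusted p under 0.05), against 5 higher and 20 lower by fry, which tests against no change and not against other genes. The matrix, p53 and endothelial lists passed by fry alone. Members named because they went against their list were picked after their values were seen. Scaled to the 42 epithelial genes, the median of all genes shifted by 1.68 and 31 of the 34 lists had a median above 0; those below 0 were basal squamous (−0.02), squamous differentiation (−0.22) and NF-kB cytokine and chemokine (−0.13). Control replicate 2 also differed from the other controls, by a median log2 value of 0.58 in ribosomal protein, 0.45 in lysyl oxidase, 0.37 in squamous differentiation, 0.34 in cholesterol, 0.33 in matrix protease, 0.24 in heat shock, 0.22 in oxidative phosphorylation and 0.21 in NF-kB genes. Smaller rises were in TGF-beta (0.18) and actin (0.16) genes, and it was lower in ATF4 and amino acid (−0.57), fatty acid (−0.33) and mitosis (−0.24) genes. Without that library, glycolysis was the list that lost its call. Directions of lists and genes in what follows are therefore relative to the TMM scale.

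Genes of epithelial adhesion and of the squamous lineage fell almost as a block. Of 29 adhesion genes, 0 rose and 27 fell (1 and 27 adjusted over the list alone), with a median log2 fold change of −1.68 (camera adjusted p = 4.46e-10; adjusted p = 0.131 with an estimated correlation). EPCAM, an epithelial adhesion molecule, fell from 199 ± 9.33 to 53.7 ± 1.28 CPM (−1.89, SE 0.09, edgeR adjusted p = 3.53e-07), and the epithelial splicing regulator ESRP1 from 218 ± 33.4 to 50 ± 1.62 CPM (−2.12, SE 0.13, edgeR adjusted p = 1.10e-06). The epithelial transcription factor GRHL2 fell from 88.4 ± 8.09 to 21.2 ± 3.93 CPM. The tight junction genes OCLN (48.2 ± 1.09 and 55.7 ± 1.75 CPM) and TJP1 (145 ± 36.6 and 118 ± 7 CPM) did not pass. Of 20 basal squamous genes, 0 rose and 19 fell, also when adjusted over the list alone (median −1.69, camera adjusted p = 2.16e-09; adjusted p = 0.176 with an estimated correlation). TP63, the master regulator of stratified epithelium, fell from 549 ± 93.3 to 120 ± 6.33 CPM (−2.19, SE 0.15, edgeR adjusted p = 1.74e-06), and the basal keratin KRT5 from 1610 ± 452 to 228 ± 11.6 CPM (−2.82, SE 0.20, edgeR adjusted p = 2.97e-06), though keratin genes can share reads that the counting divides. SOX2 did not pass, at 5.65 ± 1.06 and 5.90 ± 0.413 CPM. Of 29 squamous differentiation genes tested, 0 rose and 24 fell, or 25 adjusted over the list alone (median −1.88, camera adjusted p = 2.16e-09; adjusted p = 0.476 with an estimated correlation). The cornified envelope component CSTA fell from 98.5 ± 20 to 16.2 ± 1.21 CPM and EVPL, which encodes envoplakin, from 62.2 ± 2.25 to 18.2 ± 2.17 CPM. Over the 42 adhesion and basal squamous genes with at least 20 CPM in the controls, the log2 fold change had a median of −1.69 and an interquartile range of −2.08 to −1.19, and 40 (95.2%) fell.

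Mesenchymal genes split. Of 19 mesenchymal and EMT transcription factor genes tested, 10 rose and 5 fell, also when adjusted over the list alone (median 0.96, camera adjusted p = 0.00563; adjusted p = 0.476 with an estimated correlation). VIM, the intermediate filament vimentin and also a HEK293 marker here, rose from 2.43 ± 0.234 to 706 ± 124 CPM (log2 fold change 8.18, SE 0.21, edgeR adjusted p = 2.20e-08). CDH2, N-cadherin, rose from 4.06 ± 1.15 to 77.2 ± 5.38 CPM (4.24, SE 0.18, edgeR adjusted p = 1.46e-07), and the repressors of E-cadherin ZEB2 and ZEB1 from 0.770 ± 0.177 to 25.2 ± 1.45 and from 0.485 ± 0.375 to 30.1 ± 2.19 CPM. The ZEB1 value moved from 5.94 to 6.74 on the log2 scale without control replicate 2. SNAI2 (−1.40), TWIST2 (−1.80), S100A4 (−2.10), ITGA5 (−0.88) and LGALS1 (−2.42) fell. The list did not pass in limma on log2(FPKM + 1) (camera adjusted p = 0.6) or on ranks (camera adjusted p = 0.2), within a range of 0.00176 to 0.6 over 20 camera alternatives. Beside this list, the 13 HEK293 markers other than VIM, chosen after the largest rises had been seen, were higher too.

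Matrix genes also went both ways. Of 31 fibrillar and basement membrane genes tested, 11 rose and 16 fell (11 and 17 adjusted over the list alone); the median was −0.58, the mean 0.78, and the list did not pass (camera adjusted p = 0.444, direction up). NID1, the basement membrane linker nidogen 1, rose from 0.514 ± 0.0489 to 222 ± 19.1 CPM (log2 fold change 8.72, SE 0.17, edgeR adjusted p = 8.30e-09), FBN2, a microfibril protein, from 0.223 ± 0.117 to 107 ± 16.8 CPM, and COL6A2, a collagen VI chain, from 3.51 ± 0.920 to 118 ± 11.5 CPM. Of 23 matrix protease and inhibitor genes, 3 rose and 14 fell, or 16 adjusted over the list alone (median −0.86, camera adjusted p = 0.0189; adjusted p = 0.609 with an estimated correlation). The lysosomal protease CTSB fell from 1490 ± 202 to 312 ± 61.1 CPM (−2.25, SE 0.18, edgeR adjusted p = 4.96e-06) and the urokinase gene PLAU from 150 ± 26.1 to 50.5 ± 5.94 CPM. ADAMTS1 (4.73), TIMP1 (1.22) and MMP9 (1.58) rose on the log2 scale. Of 33 actin cytoskeleton and invadopodia genes, 3 rose and 26 fell, or 27 adjusted over the list alone (median −0.81, camera adjusted p = 0.000395; adjusted p = 0.609 with an estimated correlation). The Arp2/3 subunit ARPC2 fell from 755 ± 81.1 to 289 ± 12.1 CPM and the capping protein CAPG from 137 ± 32.7 to 34.1 ± 2.82 CPM. The formin DIAPH3 (2.25), the tropomyosin TPM2 (1.47) and the ERM protein RDX (0.52) rose. Among 17 integrin and adhesion adaptor genes, 1 rose and 11 fell, or 12 adjusted over the list alone (median −0.88, camera adjusted p = 0.000982; adjusted p = 0.547 with an estimated correlation). ITGA6 and ITGB4, which form the hemidesmosome integrin, fell from 486 ± 42.3 to 135 ± 6.16 and from 920 ± 71.1 to 284 ± 34.7 CPM. ITGB3 rose from 0.439 ± 0.387 to 1.94 ± 1.10 CPM. The falls in the protease, actin and integrin lists stood beside the lower level of the 42 epithelial genes (median −1.69). ITGA6, ITGB4 and ITGA3 of the integrin list are themselves among the 42, as is COL17A1 of the matrix list.

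Inflammatory and signalling targets were mostly lower. Of 23 NF-kB cytokine and chemokine genes tested, 0 rose and 20 fell, also when adjusted over the list alone (median −1.82, camera adjusted p = 1.20e-07; adjusted p = 0.131 with an estimated correlation). CXCL1, a neutrophil-attracting chemokine, fell from 60.7 ± 12.8 to 3.75 ± 1.21 CPM (−4.02, SE 0.24, edgeR adjusted p = 9.23e-07), and NFKBIA, the NF-kB inhibitor, from 246 ± 27.2 to 46.4 ± 4.95 CPM (−2.41, SE 0.13, edgeR adjusted p = 4.61e-07). CCL5 was at 55.2 ± 5.97 and 54.2 ± 3.97 CPM and did not pass. Of 19 antigen presentation genes, 0 rose and 18 fell, also when adjusted over the list alone (median −1.28, camera adjusted p = 1.28e-05; adjusted p = 0.588 with an estimated correlation), among them the immunoproteasome subunits PSMB9 (63.0 ± 9.21 to 15.5 ± 0.345 CPM) and PSMB8 (71.7 ± 12.1 to 19.0 ± 2.33 CPM). The list was higher in control replicate 2 than in the other controls by a median of 0.62 on the log2 scale, with CD74, singled out after its values were seen, at 95.9 CPM there against 11.4 and 16.1; the list passed without that library too. Interferon-stimulated genes were mixed, with 6 higher and 19 lower of 38, also when adjusted over the list alone (median −0.41, camera adjusted p = 0.00337; adjusted p = 0.588 with an estimated correlation). PARP14 fell from 163 ± 6.79 to 47.1 ± 3.63 CPM, while USP18 (0.73) and IFIT1 (0.74) rose. Of 23 EGFR and MAPK feedback targets, 2 rose and 16 fell, also when adjusted over the list alone (median −0.91, camera adjusted p = 0.00103; adjusted p = 0.374 with an estimated correlation). PHLDA1 fell from 271 ± 11 to 73.5 ± 5.94 CPM, while SPRY2 (1.88) and EPHA4 (1.33) rose. TGF-beta targets showed 2 higher and 12 lower of 22 (median −0.54, camera adjusted p = 0.0153; adjusted p = 0.609 with an estimated correlation) and YAP and TEAD targets 2 higher and 11 lower of 22 (median −0.34, camera adjusted p = 0.0367; adjusted p = 0.637 with an estimated correlation), with the same counts adjusted over the list alone. ID1, a bHLH inhibitor induced by BMP signalling, fell from 573 ± 155 to 51.2 ± 16.2 CPM (−3.48, SE 0.27, edgeR adjusted p = 5.14e-06), and its relative ID2 rose from 18.0 ± 4.40 to 89.4 ± 7.01 CPM. LTBP1 (0.95) rose too. AMOTL2 fell from 485 ± 63.3 to 142 ± 25.3 CPM, while ANKRD1 (4.33) and GADD45A (0.42) rose. The YAP and TEAD list did not pass without LOXL2 shRNA replicate 2 (camera adjusted p = 0.0725, range 0.00567 to 0.637 over 20 camera alternatives). In these libraries the 42 epithelial genes stood at a median of 31.0% of their control level.

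Metabolic lists differed in how far they moved. Of 26 NRF2 targets, 0 rose and 24 fell, also when adjusted over the list alone (median −1.51, camera adjusted p = 4.46e-10; adjusted p = 0.131 with an estimated correlation). NQO1, a quinone reductase, fell from 291 ± 25.3 to 60.9 ± 6.56 CPM (−2.26, SE 0.12, edgeR adjusted p = 5.34e-07), and the glutathione peroxidase GPX2 from 68.6 ± 8.61 to 13.7 ± 2.30 CPM. HMOX1 (16.5 ± 1.98 and 17.0 ± 3.24 CPM) did not pass. Of 25 hypoxia targets, 0 rose and 18 fell, or 19 adjusted over the list alone (median −1.09, camera adjusted p = 0.00103; adjusted p = 0.617 with an estimated correlation), with VEGFA at 624 ± 73.6 and 308 ± 32.4 CPM and DDIT4 at 1410 ± 215 and 505 ± 16.9 CPM. Of 24 glycolysis genes, 2 rose and 14 fell, also when adjusted over the list alone (median −0.51, camera adjusted p = 0.0405; adjusted p = 0.821 with an estimated correlation). The glucose transporter SLC2A1 fell from 1590 ± 700 to 247 ± 97.0 CPM (−2.69, SE 0.37, edgeR adjusted p = 0.000275), and its relative SLC2A3 rose from 3.92 ± 1.31 to 59.5 ± 14.3 CPM (3.92, SE 0.25, edgeR adjusted p = 1.42e-06), as did LDHB (0.34). The glycolysis list did not pass without control replicate 2 (camera adjusted p = 0.128) or without LOXL2 shRNA replicate 2 (camera adjusted p = 0.0825), within a range of 0.0022 to 0.821 over 20 camera alternatives, and hypoxia targets were higher in control replicate 2 than in the other controls by a median of 0.82 on the log2 scale. Of 25 cholesterol synthesis and uptake genes, 1 rose and 18 fell (2 and 19 adjusted over the list alone; median −0.82, camera adjusted p = 0.000886; adjusted p = 0.617 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell from 1430 ± 169 to 342 ± 97.8 CPM, while SC5D (0.54) rose. Fatty acid synthesis had 2 higher and 10 lower of 13, also when adjusted over the list alone (median −0.93, camera adjusted p = 0.0353; adjusted p = 0.609 with an estimated correlation), with the desaturase SCD down from 1540 ± 267 to 598 ± 45.1 CPM and FADS2 (1.44) and GPAM (0.79) up. Nuclear oxidative phosphorylation genes did not pass as a list: 9 of 37 rose and 7 fell (7 and 5 adjusted over the list alone; median 0.08, camera direction down, adjusted p = 0.891). The 42 epithelial genes fell by a larger median, −1.69, than any of these lists.

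Stress-response lists did not pass. ATF4 and amino acid genes had 12 higher and 5 lower of 26, also when adjusted over the list alone (median 0.36, camera adjusted p = 0.828). ASNS, asparagine synthetase, rose from 159 ± 36.2 to 540 ± 71.6 CPM and CTH, cystathionine gamma-lyase, from 11 ± 3.20 to 76.7 ± 14.2 CPM. The members that fell were SLC7A5, a large neutral amino acid transporter (4310 ± 510 to 1140 ± 182 CPM), its partner SLC3A2 (−1.33), SLC7A11 (−1.01), CEBPB (−1.35) and DDIT3 (−0.41). Of 20 unfolded protein response genes, 4 rose (SDF2L1, HYOU1, MANF and XBP1) and 4 fell (HSPA5, PDIA3, PDIA6 and ATF6), or 3 and 3 adjusted over the list alone (median 0.09, camera direction down, adjusted p = 0.807). The chaperone HSPA5, at 1370 ± 129 and 922 ± 176 CPM, did not pass without LOXL2 shRNA replicate 2 (−0.51, edgeR adjusted p = 0.0606) or 3 (−0.48, edgeR adjusted p = 0.0719), with total-count scaling (−0.35, edgeR adjusted p = 0.0574) or in limma on log2(FPKM + 1) without a filter (−0.36, limma adjusted p = 0.054), within a range of 0.000535 to 0.57 over 19 alternatives, the highest in the test against a 1.5-fold change. The stress sensor ATF6 (−0.46) did not pass with total-count scaling (−0.25, edgeR adjusted p = 0.164), in the test against a 1.5-fold change (edgeR adjusted p = 0.984) or in limma on FPKM (−0.23 to −0.22, limma adjusted p = 0.206 to 0.246), within a range of 6.59e-05 to 0.984 over 19 alternatives. Of 15 heat shock genes, 3 rose and 6 fell, also when adjusted over the list alone (median −0.20, camera adjusted p = 0.418). HSPB1 fell from 466 ± 115 to 120 ± 23.6 CPM, and HSPA4L (2.52), FKBP4 (0.63) and HSP90AA1 (0.34) rose. HEK293 markers, chosen after the largest rises had been seen, were higher beside these lists as well, with CKB at 21.5 ± 3.36 and 532 ± 11.7 CPM.

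Genes of DNA replication rose together. Of 34 replication and S phase genes, 31 rose and 1 fell, also when adjusted over the list alone (median 1.0, camera adjusted p = 6.11e-09; adjusted p = 0.131 with an estimated correlation). The origin-firing factor MCM10 rose from 14 ± 1.31 to 79.2 ± 6.26 CPM (2.50, SE 0.12, edgeR adjusted p = 2.57e-07), and RRM1, a ribonucleotide reductase subunit, from 57.2 ± 3.72 to 215 ± 19.9 CPM. TYMS fell from 172 ± 4.29 to 133 ± 10.7 CPM (−0.37, SE 0.10, edgeR adjusted p = 0.00809). Of 34 mitosis genes, 25 rose and 1 fell, also when adjusted over the list alone (median 0.62, camera adjusted p = 0.00308; adjusted p = 0.609 with an estimated correlation). The kinase gene CDK1 rose from 39.1 ± 1.95 to 103 ± 6.41 CPM and the spindle motor KIF11 from 53.3 ± 4.75 to 129 ± 6.57 CPM, while the phosphatase CDC25B (−1.0) fell. Of 9 replication-dependent histone genes tested, 1 rose, H2BC5, from 0.149 ± 0.129 to 1.12 ± 0.0291 CPM, also when adjusted over the list alone (list median −0.04, mean 0.22, camera direction down, adjusted p = 0.807). Ribosomal protein genes did not pass as a list, with 10 of 43 higher and 8 lower, or 9 and 6 adjusted over the list alone (median 0.06, camera direction down, adjusted p = 0.652). Of 24 p53 targets, 13 rose and 5 fell, also when adjusted over the list alone (median 0.39, camera adjusted p = 0.614). CCNG1 rose from 33.7 ± 5.05 to 178 ± 19.0 CPM, and GDF15 (−1.41), PHLDA3 (−1.20), FAS (−0.79), CDKN1A (−0.57) and TNFRSF10B (−0.48) fell. Of 21 apoptosis regulators, 2 rose and 14 fell, also when adjusted over the list alone (median −0.79, camera adjusted p = 0.0153; adjusted p = 0.476 with an estimated correlation). Those that rose were the BH3-only gene PMAIP1 (40.3 ± 6.93 to 194 ± 12.9 CPM) and the survival gene BCL2 (5.10 ± 0.545 to 16.9 ± 1.49 CPM). CDKN2A, the CDK inhibitor gene and 1 of the HEK293 markers, was at 0.700 ± 0.140 CPM in the controls and 128 ± 25.9 CPM in the same LOXL2 shRNA libraries.

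**Figure D3:**
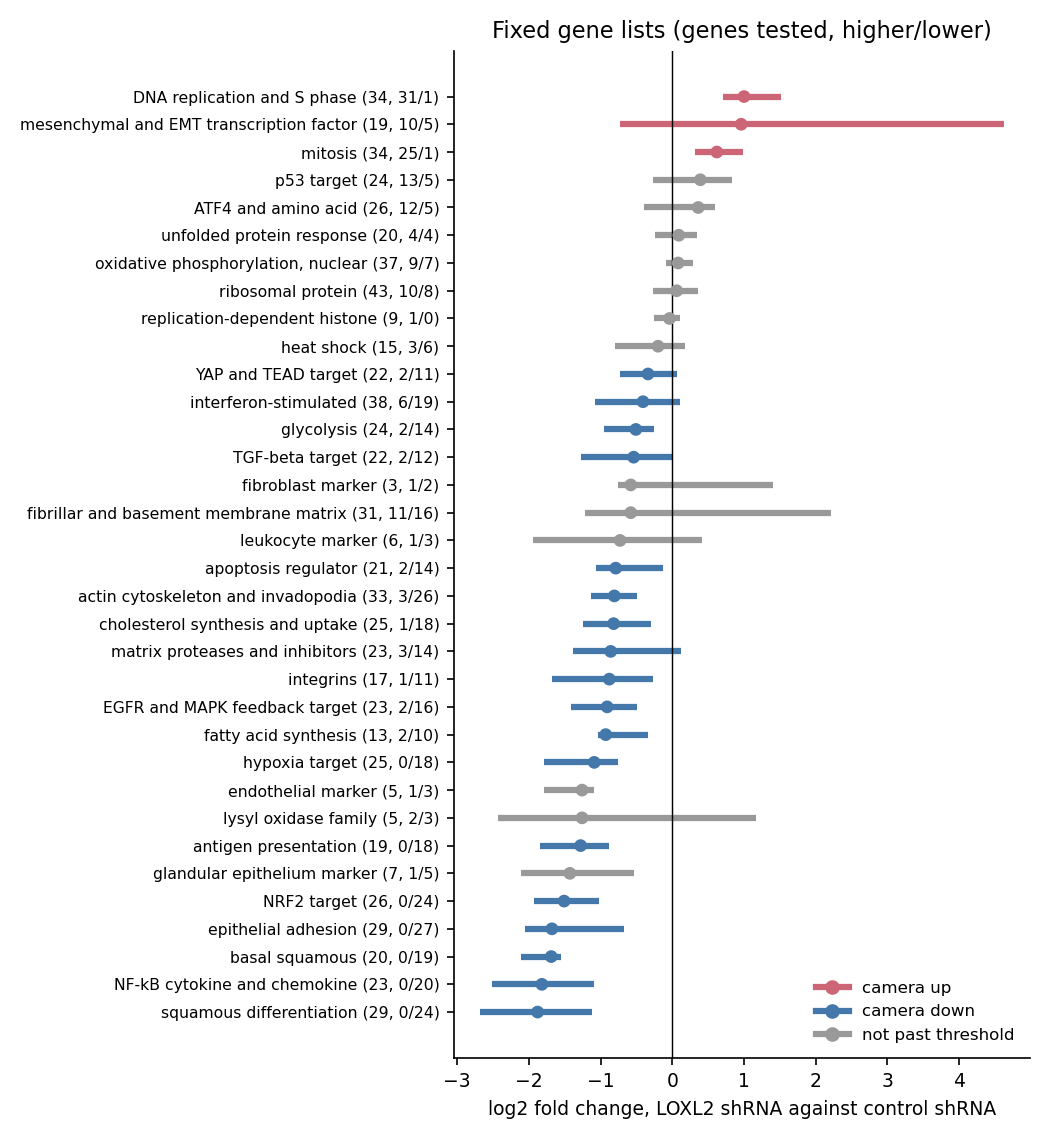
Log2 fold change of LOXL2 shRNA against control shRNA for each of the 34 fixed lists, on the TMM scale, with a point at the list median, a bar over its interquartile range and, in brackets, the genes tested and the number higher and lower. The highest median was that of replication and S phase (1.0) and the lowest that of squamous differentiation (−1.88); red and blue mark lists past the threshold by camera, and scaled to the 42 epithelial genes 31 of the 34 medians lay above 0.

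Marker lists of cell types that a culture could hold gave few detected genes. Fibroblast markers had 3 tested genes, with COL3A1 higher (1.03 ± 0.147 to 10.9 ± 1.10 CPM) and COL1A1 (87.9 ± 6.81 to 58.6 ± 5.76 CPM) and FAP (14.3 ± 3.74 to 7.46 ± 1.34 CPM) lower. The median was −0.58, the mean 0.62 and the camera adjusted p 0.891 (direction up). Among leukocyte markers, CD14 (−3.12), LAPTM5 (−2.09) and CD68 (−1.52, and −0.88 without control replicate 2) fell; CD68 did not pass without LOXL2 shRNA replicate 3 (−1.40, edgeR adjusted p = 0.0543, range 4.46e-05 to 0.0547 over 19 alternatives, the highest in the test against a 1.5-fold change). That list had a median of −0.73 and a mean of 0.10 (camera direction down, adjusted p = 0.614). Of 5 endothelial markers tested, ESAM rose (2.19) and VWF (−3.01), ERG (−1.79) and PECAM1 (−1.10) fell (median −1.26, camera adjusted p = 0.253). Without control replicate 2, which held 11 of its 13 control counts, ESAM was higher by a ratio of 20.6 (95% exact interval 5.49 to 173). Of 7 glandular epithelium markers tested, the keratins KRT7 (1900 ± 156 to 578 ± 55.1 CPM), KRT8 (−1.43), KRT18 (−1.12) and KRT19 (−2.76) and the mucin MUC1 (−2.50) fell, KRT18 and KRT19 being named after their values were seen. CDX2, an intestinal transcription factor, rose from 0 counts to 16.1 ± 3.6 CPM (at least 48.6-fold higher). The median was −1.43, the mean 0.12 and the camera adjusted p 0.0917 (direction down). It passed in 8 of 20 camera alternatives (range 0.00777 to 0.609), among them without control replicate 1 (camera adjusted p = 0.0376) and without LOXL2 shRNA replicate 1 (camera adjusted p = 0.0413). Counts of members higher and lower in these 4 lists were the same adjusted over the list alone.

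Markers of HEK293, a human embryonic kidney line with neuronal traits, were looked at after the largest rises had been seen, so their direction is not independent evidence. All 14 genes chosen were higher in the LOXL2 shRNA libraries, with a median log2 fold change of 7.01 when the 8 genes without a control count were set at their bound (10.23 as fitted). NEFM, a neurofilament, rose from 0.185 ± 0.0665 to 121 ± 16.8 CPM (edgeR adjusted p = 2.20e-08). UCHL1, a neuronal ubiquitin hydrolase, had 2 control counts and reached 84.6 ± 12.4 CPM, a ratio of 1150 (95% exact interval 319 to 9540, counting error only). SALL1 and PAX2, transcription factors of kidney development, had 0 control counts and reached 34.4 ± 0.922 and 7.05 ± 0.315 CPM, at least 104-fold and 21.3-fold higher. Of the 14, VIM and CKB were above 1 CPM in the controls.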

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

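Scaling to the epithelial genes was chosen after the data were seen; the other alternatives were set before. LOXL2 stayed lower and past the threshold in all 19 alternatives set before (log2 fold change −3.60 to −3.18, adjusted p 4.54e-89 to 3.25e-05). Of the 8894 calls, DESeq2 kept 8418, the replicate block 8363 and limma on log2(FPKM + 1) 7107 of 8280 with a value, and no alternative set before called a gene in the opposite direction. Replicate numbers do not pair the libraries (r −0.261, −0.138 and 0.190 for equal numbers).

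Leaving out 1 library at a time gave 7669 to 9610 genes changed, 4213 to 5184 higher and 3456 to 4426 lower, 2462 to 2610 higher and 1579 to 1867 lower by at least 1 on the log2 scale, LOXL2 at −3.60 to −3.32, and 3 lists higher and 16 to 19 lower. Genes lower by at least 1 numbered 952 with limma on log2(FPKM + 1) and 956 without its filter, against 1683; the cause was not tested. The test against a 1.5-fold change, stricter by construction, called 4761 genes, 2794 higher and 1967 lower. Total-count scaling and limma moved the median of all genes by 0.22 and 0.21.

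Scaled to the epithelial genes, 12965 genes were higher and 279 lower, 11620 and 122 of them by at least 1, and LOX reversed to 0.41; the scaling lifts all genes by construction. With the correlation estimated per list, 0 lists were higher and 0 lower; with fry 5 lists were higher. Among lists, 29 values lost and 14 gained the threshold against 669 that did neither; among named genes, 26 lost it, LOX reversed and 2701 did neither. The epithelial scaling enters these counts for the lysyl oxidase family alone; over all genes it called 2844 of the 8894 in the opposite direction. At this depth the simulation, with 200 genes changed, recovered 24% of 1.5-fold changes. With 8894 genes called in the data, the adjustment is less strict than in the simulation. The 24% is therefore not the share found in the data, though small changes can still be missed.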

Other observations

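The families, neighbours, HEK293 markers, and the tests on squamous share, cell state and depth of control replicate 2 were chosen after results were seen. Gene families named by symbol root, 238 in all, were compared with the other tested genes by Fisher's exact test, two-sided. Each family was tested for members higher and for members lower, and both sets of p-values were adjusted together over the 238 families. Zinc finger genes (ZNF) had 209 higher and 63 lower of 456 (median log2 fold change 0.32, Fisher's exact adjusted p = 1.34e-11 for few lower). HOX genes had 25 higher and 1 lower of 35 (median 2.03, Fisher's exact adjusted p = 0.000511), ADAMTS proteases 13 and 1 of 16 (median 4.58, exact adjusted p = 0.00805) and CACNA calcium channel subunits 8 and 0 of 9 (median 5.17, exact adjusted p = 0.0389). Keratins had 0 higher and 18 lower of 21 (median −1.68, exact adjusted p = 1.41e-05) and S100 genes 1 and 13 of 15 (median −1.86, exact adjusted p = 0.000511). RAB genes passed with 15 and 35 of 67 (exact adjusted p = 0.00472) and ANXA genes with 1 and 9 of 11 (exact adjusted p = 0.0191). For few lower, CEP genes passed with 21 and 2 of 38 (exact adjusted p = 0.0213) and NUP genes with 10 and 0 of 22 (exact adjusted p = 0.0465). Fisher's exact test counts the genes of a family as independent, though related genes can change together. Of the fixed lists, 0 passed by camera once a correlation was estimated per list. The family p-values make no such allowance and may be too small. Scaling to the epithelial genes adds 1.68 to the median of all genes, and the falls in keratins and S100 genes are near that shift. The genes that set it include keratins such as KRT5 and also S100A2, so part of this nearness is built in.

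Genes silent in the controls and expressed with LOXL2 shRNA lay next to each other on the chromosomes more than random placement gives. Under 0.1 CPM in the controls and at least 1 CPM with LOXL2 shRNA were 433 genes. In the gene order of assembly GRCh38.p14 they formed 59 adjacent pairs among 14284 genes of at least 1 CPM in a group. Random placements gave 13.1 expected and at most 27 (permutation test, one-sided p = 1e-04, the smallest that 10000 placements can give). Such placements ignore that related genes can lie side by side, so the excess was not tested against clustering of gene families. EPDR1, STARD3NL and AMPH, singled out after their values were seen, are neighbours with control counts of 0, 0 and 0; 0, 2 and 0; and 0, 0 and 0, and LOXL2 shRNA counts of 33, 60 and 35; 232, 226 and 227; and 119, 89 and 69 in replicates 1, 2 and 3.

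The 322 genes under 0.2 CPM in the controls and over 5 CPM with LOXL2 shRNA raise the question of RNA from other cells; a label swap between the groups is excluded, since 0 libraries had LOXL2 on the other group's side. RNA of a HEK293-like line, a line used to package lentivirus, may be present: of 16 neuronal and embryonic kidney genes listed without looking at their values, 11 were tested and 9 were higher (median 2.91), against 4783 of all 14314 genes tested, while 7 of the 11 were above 1 CPM in the controls. ELAVL2 and SYT1 did not pass on the TMM scale. EMX2, with 1 control count, could be tested only because of its counts in the LOXL2 shRNA libraries. HOXD10 and HOXD11 belong to the HOX family, with 25 higher and 1 lower of 35. ADAMTS genes, with 13 higher and 1 lower of 16, rose as well. Both families were picked after their values were seen. A rise was thus not particular to this list, and the 9 genes do not single out a HEK293-like line. Scaled to the epithelial genes, all 11 were higher (median 4.59), but on that scale 12965 of all 14314 genes were higher. STMN2, GAP43, ELAVL3, ELAVL4 and SOX11 had too few counts in both groups to be tested. Without a HEK293 profile, genes that did not pass or were not tested cannot be weighed for or against such a line. A smaller share of squamous cells could accompany such RNA. Of the 42 epithelial genes, 71.4% lay within 1 log2 unit of their median, a bound set after the data were seen. Among all 14314 genes tested, 2478 were called higher and 1683 lower by at least 1 on the log2 scale. The 71.4% was therefore not shown to be particular to epithelial genes, and it does not decide on a smaller share. A change of cell state after LOXL2 silencing cannot be told apart from RNA of other cells by the 322 genes. Such a change would switch on silent genes too, and no HEK293 profile was analysed here.

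The LOXL2 fall is larger than the epithelial fall. LOXL2 lay −2.16 SDs from the mean of the epithelial genes, with 1 of them, KRT15 (−4.27), lower. The bound on that distance was set after the data were seen. The log2 fold change of −1.80 after scaling to those genes was tested against cells that kept LOXL2 at the control level. It restates that distance and is no second test. On that scale 7 adhesion and 6 basal squamous genes were called lower too. Beyond those lists, CLCA2 of stratified epithelium (−4.74) and S100A7 of the squamous differentiation list (−3.99) fell further than LOXL2 (−3.46). Both were picked after their values were seen, and the squamous differentiation list had a median of −1.88. A smaller squamous share as the whole cause of the LOXL2 fall is therefore not excluded. Silencing in the squamous cells, or a low LOXL2 level in other cells beside it, stays open.

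Control replicate 2 stood apart from control replicates 1 and 3. Its depth, 9805836 counts (9.81 in the unit of the test), lies between theirs and so is excluded. A hypoxia or nutrient state of the culture may account for it: the hypoxia list was higher by a median of 0.82 on the log2 scale, at percentile 100 of random lists, and glycolysis by 0.71. Percentile 100 was also reached by glycolysis, cholesterol (0.34), antigen presentation (0.62) and ribosomal protein genes (0.58), so it is not particular to hypoxia. Oxidative phosphorylation genes were higher as well (0.22, percentile 99.97). ATF4 and amino acid genes (−0.57, percentile 0), fatty acid synthesis (−0.33) and mitosis (−0.24) were lower, and a shortage of amino acids would raise the ATF4 list. Of the 10 splits of the 6 libraries, the real 1 changed 8894 genes and the highest other 0 (edgeR; 9430 and 2 to 151 at an unadjusted p under 0.05), too few splits for a share under 0.05.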
